A study of Mus musculus with 54 samples.

How the data were processed

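Whole cerebellum from mice was described in the labels as Control, RnaseH2B Nes-cre, Atm Nes-cre, p53 or compound genotypes at P5, P28 and 9 weeks. The labels name TRIzol extraction, a TruSeq stranded total RNA kit, paired-end adaptors and a HiSeq instrument, and they mark the P28 libraries as poly-A selected. Per the submitters' processing notes, Trim Galore, STAR, BWA, HTSeq and limma were used with the mm9 build. Which step each did, and their versions, were not given in the sources used here. Ages were sequenced from different kinds of RNA and were never joined in a fit.

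The deposited log2 CPM values were used as the authors gave them. Columns were matched to samples by genotype, age and replicate number, and 0 columns were left without a sample. Whole reads were recovered from the P28 and P5 log2 CPM values, with 100% of them within 0.01 of a whole number and a mean prior of 0.5 read. Depth at 9 weeks could not be recovered. The deposited FPKM values served as a second scale, after adding 0.1 or 1 and taking the log2. At 9 weeks the deposited FPKM values were not plain FPKM but shifted by the authors, with 30976 negative values, which were set to 0 before the log2.

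At 9 weeks the samples fell into 2 runs by the codes in their labels. Codes 11 to 16 held controls 1 to 3 and Rnaseh2b 1 to 3, and codes 50 to 58 held the other 4 of each group. The means of both runs were equal for every gene in the deposited values, with a largest difference of 3.12e-09 log2 CPM and 3.17e-05 FPKM, so the authors had already taken out the run difference. Spread between the 9-week samples is therefore slightly underestimated, and within-run results stand beside the 9-week result.

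The tables held 17827 features at 9 weeks, 19432 at P28 and 19235 at P5. Of the gene names, 23 in each log2 CPM table had turned into dates and were not used by name. FPKM was infinite or missing for 353 features at 9 weeks and 354 at P5. Some list members carry older symbols in the tables, and these were matched through the synonyms of a reference gene table for Tigar, Pidd1, Trp53cor1, Ifi27, Cgas, Sting1 and Myrf. No copies were seen among libraries of the same group at P28 and P5, where the lowest chi-square per degree of freedom between 2 libraries was 9.64 and 16.9. Pairs across groups and 9-week libraries were not compared in this way.

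Genes were tested when they reached 1 CPM in at least as many libraries as the smallest group of the age, which was 7 at 9 weeks, 5 at P28 and 3 at P5. This left 15078 genes at 9 weeks, 16530 at P28 and 15421 at P5. All groups of an age were fitted together by limma with a variance trend, in limma 3.58.1 under R 4.3.3. P values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. Here rose and fell are kept for called genes and lists. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

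For the lists of genes, 29 were written from textbook knowledge before the data were examined, as were the comparisons, the filter, the rule for naming genes and most of the alternative settings. Each list was tested by camera with a preset correlation of 0.01 and a second time with an estimated correlation, with adjustment over the lists of a comparison. Members were counted by their genome-wide adjusted p, and again with adjustment over the list alone. A list value, the mean over members of log2 CPM less the control mean, was compared between libraries by exact two-sided permutation tests. With 5 libraries a side the smallest possible exact permutation p is 0.00794, with 4 and 3 it is 0.0286, and with 3 a side it is 0.1.

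Genes are named by a rule. Engineered genes are always given. Of the called genes with a mean of at least 1 log2 CPM and with every library of the first group on the same side of the mean of the second, the 8 largest rises and 8 largest falls qualify, without model names and mitochondrial tRNAs. Each list adds up to 4 called members with the smallest adjusted p. The 4 most expressed members of the p53 target list and the interferon-stimulated list may also be named, called or not. For differences of effects the rule on sides was dropped. Some genes that the rule would name are not reported. The text goes down these ranks, stops before their end and mostly passes over pseudogenes, whose reads may be shared with near-identical genes. A list of midbrain genes, a list of ventral midbrain genes and the tests that use them were added after the data had been seen. Of the midbrain list 10 members were tested at P5, 9 at P28 and 4 at 9 weeks, so its values do not cover the same genes at each age.

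Errors after the sign ± are standard errors of the limma fit for fold changes and standard deviations for means of libraries. Unless given otherwise, every library of the first group lay on the stated side of the mean of the second. The labels do not say that replicates are separate animals, so p values measure only the spread between these samples. In a self-test on simulated values with the spread of each gene, 100 genes were shifted by 1 log2, and limma found 97% of them in the 9-week comparison, 88% at P28 and 80% at P5 for Rnaseh2b against control. For shifts of 0.5 log2 these shares were 78%, 64% and 50%. For the differences of effects at P5 the shares at 1 log2 were 68% with Atm and 60% with p53. The simulated noise was independent between genes and held no libraries that stand apart, so these shares may not carry over to the real data.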

Results

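RNA from whole mouse cerebellum was compared between controls and mutants at 3 ages. Rnaseh2b encodes a subunit of RNase H2, which removes ribonucleotides from DNA. Atm encodes a kinase that answers DNA breaks, and Trp53 encodes p53, a transcription factor of the same response. At P5 there were 3 control, 3 Rnaseh2b, 3 Atm and 3 p53 libraries, with 4 Rnaseh2b/Atm and 4 Rnaseh2b/p53 libraries. At P28 there were 5 libraries each of control, Rnaseh2b, Atm and Rnaseh2b/Atm. The 9-week set had 7 control and 7 Rnaseh2b libraries. Reads in genes ran from 24.1 M to 89.7 M at P28, with a median of 62.9 M. At P5 they ran from 48.2 M to 95.1 M, with a median of 80.4 M, except for replicate 3 of Rnaseh2b/p53 at 711 M.

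Rnaseh2b transcripts were lower in every group labelled with its deletion. At P5 the mean was 4.27 ± 0.46 log2 CPM in control and 2.01 ± 0.13 in Rnaseh2b, 1.91 ± 0.08 in Rnaseh2b/Atm and 2.20 ± 0.08 in Rnaseh2b/p53. At P28 it was 2.84 ± 0.09 in control, 1.12 ± 0.18 in Rnaseh2b and 0.90 ± 0.24 in Rnaseh2b/Atm. At 9 weeks it was 3.47 ± 0.14 in control and 2.45 ± 0.23 in Rnaseh2b, a fall of −1.02 ± 0.10 log2 (limma, adjusted p = 3.1e-05). Trp53 was 3.71 ± 0.61 in P5 control, 1.64 ± 0.31 in p53 and 2.02 ± 0.21 in Rnaseh2b/p53. Atm behaved differently between the groups carrying its label. In P28 libraries labelled Atm it was 4.79 ± 0.15, against 4.83 ± 0.06 in control, a difference of −0.04 ± 0.07 that was not called (limma, adjusted p = 0.73). In P28 Rnaseh2b/Atm it was 4.05 ± 0.05, a fall of −0.78 ± 0.07 against control (limma, adjusted p = 7.5e-09). At P5 it was 5.87 ± 0.46 in control, 5.58 ± 0.50 in libraries labelled Atm and 5.54 ± 0.19 in Rnaseh2b/Atm, and neither difference was called. The P5 Rnaseh2b/Atm libraries ran from 5.28 to 5.70, below control 1 (6.22) and control 3 (6.05). Control 2 lay within that range, at 5.35, so a lower level there is not excluded. A deletion of a few exons need not lower the whole transcript, so the Atm genotype rests on the labels, and the groups are called libraries labelled Atm here.

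**Figure D1:**
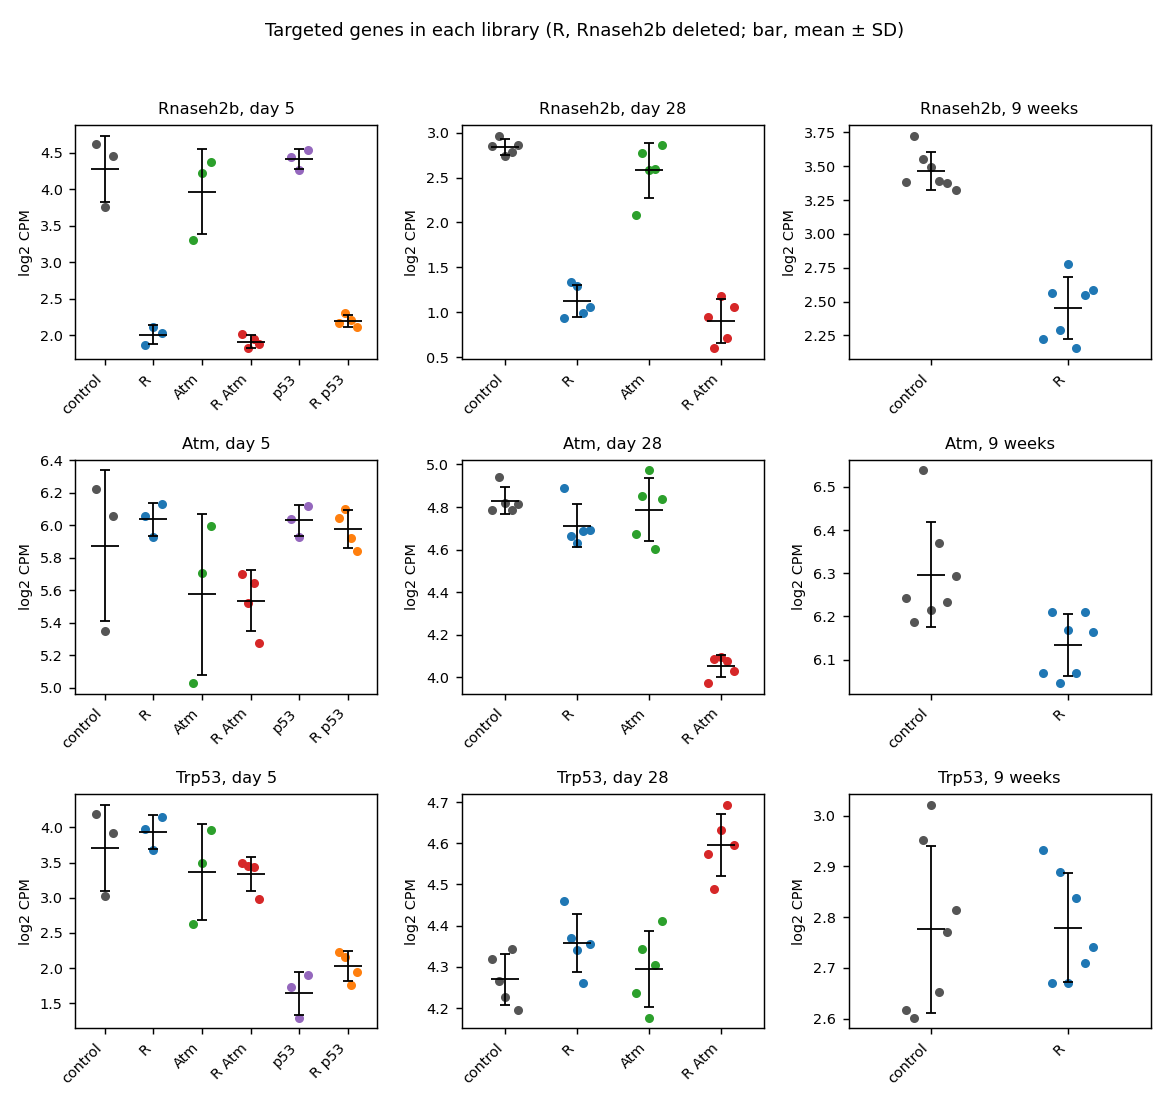
Log2 CPM of Rnaseh2b, Atm and Trp53 in every group at each age, with R for Rnaseh2b deleted. Points are libraries and bars are means ± SD, for example 2.01 ± 0.13 for Rnaseh2b in the P5 Rnaseh2b group.

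The P5 comparison of Rnaseh2b with control asked what loss of RNase H2 changes while granule neurons are still being made. Of 15421 genes, 46 rose and 59 fell (limma, n = 3 and 3). Many falls were gene models, to which the rules on names and sides were not applied. Examples were Gm3500 (−2.77 ± 0.43 log2), Gm3194 (−2.57 ± 0.40) and Gm3558 (−2.49 ± 0.40). These also fell in Rnaseh2b/p53 against the same controls and rose in P28 libraries labelled Atm. The 59 falls therefore need not be separate effects. Among p53 targets 3 of 34 rose, 31 were not called, and 10 rose when adjusted over the list alone. They were Ccng1, a cyclin induced by p53 (0.53 ± 0.10 log2, limma adjusted p = 0.021), Gm16197, the p53-induced non-coding RNA Trp53cor1 (3.26 ± 0.62), and Pmaip1, a trigger of apoptosis (2.18 ± 0.44). The list had a median of 0.27 log2 (camera, adjusted p = 4.82e-06), with adjusted p = 0.0608 with an estimated correlation. Its value was 0.45 ± 0.03 above control, with both groups apart (exact permutation p = 0.1).

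Of 30 interferon-stimulated genes, 1 rose and 29 were not called at P5, while 17 rose and 1 fell when adjusted over the list alone. The called gene was Herc6, a ligase that attaches the interferon-induced ISG15 (0.995 ± 0.20 log2, n = 3 and 3). The list had a median of 0.57 log2 (camera, adjusted p = 1.14e-10), with adjusted p = 0.277 with an estimated correlation and an exact permutation p of 0.2 for the list value. Mavs, the adaptor of RNA sensors on mitochondria, rose by 0.38 ± 0.07. Among other genes that the naming rule allows, the largest rises were in Myh3, an embryonic myosin (3.30 ± 0.49), Cdh15, a cadherin (1.68 ± 0.24), and Col14a1, a collagen (1.21 ± 0.24). Myog (5.79 ± 1.22) and Mylpf (1.97 ± 0.36), also muscle genes but of low expression, rose as well. They were named after their values were seen, and no list of muscle genes was tested. Beyond Rnaseh2b itself (−2.27 ± 0.23), the falls included Dera, an enzyme of deoxyribose breakdown (−0.94 ± 0.14), and Rpl15-ps2 (−2.27 ± 0.33), whose reads may be shared with related genes. Dera also fell by 1.02 in p53 and by 1.03 in Rnaseh2b/p53, all against the same 3 controls.

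This P5 result was fragile. With only both groups in the fit, 0 genes were called (limma, 829 at an unadjusted p below 0.05), and voom on recovered reads called 65. By limma 251 genes were called without control 1, 1 without control 2, 3 without control 3, 62 without Rnaseh2b 2 and 1 without Rnaseh2b 3. With log2 of FPKM plus 1 the split was 60 higher and 46 lower. The female transcript Xist was high in 3 of 3 controls and 1 of 3 Rnaseh2b libraries, and 34 genes were called with Xist as a covariate. The list of medulla and pons genes was 2.73 ± 1.19 log2 above control in Rnaseh2b, where the controls had an SD of 3.30. The midbrain list was at −2.22 ± 1.76 in Rnaseh2b, against an SD of 0.43 in control, and with it as a covariate 1 gene was called.

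**Figure D2:**
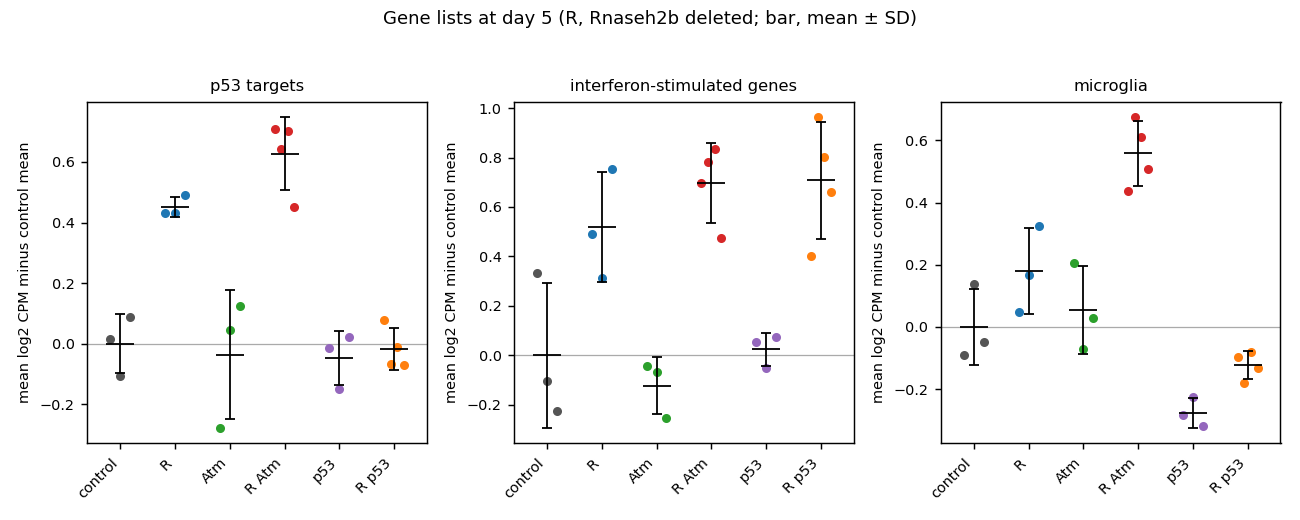
Values of the p53 target, interferon-stimulated and microglia lists in P5 libraries, in log2 relative to the control mean, with R for Rnaseh2b deleted. Points are libraries and bars are means ± SD, for example 0.63 ± 0.12 for p53 targets in Rnaseh2b/Atm.

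The P5 libraries labelled Atm were set against control to ask what the Atm label alone changed. No gene was called (limma, 0 of 15421, smallest adjusted p = 0.763, n = 3 and 3), with 435 genes at an unadjusted p below 0.05 and 0 called by voom. Without control 2 or without control 3 there was 1. Cell cycle genes had a median of −0.62 log2 (camera, adjusted p = 3.31e-08), with adjusted p = 0.824 with an estimated correlation, and none of 31 members was called. The cell cycle list value had an exact permutation p of 0.5. Neither p53 targets (median −0.03, camera adjusted p = 0.793) nor interferon-stimulated genes (−0.11, camera adjusted p = 0.127) were called as lists. Control 2 and Atm 1 stood apart from all other P5 libraries. Without both, on 2 libraries a side, the medians were −0.32 for cell cycle, −0.21 for interferon-stimulated genes and −1.55 for choroid plexus genes, and camera with the preset correlation called these and some other lists lower. All had an adjusted p of 0.9445 with an estimated correlation (camera).

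The comparison of p53 with control at P5 asked what loss of p53 alone changed. Only 12 genes rose and 15 fell (limma, n = 3 and 3). Trp53 fell by 2.07 ± 0.31 (limma, adjusted p = 0.014). The other falls included Synpo2, an actin-binding protein (−1.48 ± 0.24), Dera (−1.02 ± 0.14), Olfml1, a secreted protein (−0.92 ± 0.16), and Manba, a lysosomal mannosidase (−0.84 ± 0.13). Trim11, a ubiquitin ligase (0.64 ± 0.11), and Cuedc1 (0.50 ± 0.10) rose. None of 34 p53 targets was called, 1 fell when adjusted over the list alone, and the median was −0.02 (camera, adjusted p = 0.116). Of 21 microglia genes none was called, 4 fell when adjusted over the list alone, and the median was −0.27 (camera, adjusted p = 7.85e-10), with adjusted p = 0.157 with an estimated correlation. The call count was 3 without control 2, 5 without control 3, 5 without p53 1, 4 without p53 2 and 6 without p53 3. It was 3 with only both groups in the fit and 41 with the medulla and pons list as a covariate.

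The comparison of Rnaseh2b/Atm with libraries labelled Atm at P5 asked what Rnaseh2b deletion changed on the Atm background. Here 1154 genes rose and 311 fell (limma, n = 4 and 3). Of 34 p53 targets, 13 rose, none fell and 21 were not called, and 19 rose when adjusted over the list alone. Ccng1 rose by 1.08 ± 0.09 log2 (limma, adjusted p = 1.1e-05), Ephx1, an epoxide hydrolase, by 1.45 ± 0.12, Dcxr, a sugar reductase, by 1.52 ± 0.15, and Pmaip1 by 3.14 ± 0.42. The median of 0.34 held with both kinds of correlation (camera, adjusted p = 4.45e-10, and adjusted p = 0.00741 with an estimated correlation). Without control 2 and Atm 1, which stood apart, adjusted p was 0.123 with an estimated correlation (camera). The list value had an exact permutation p of 0.0286, or 0.08 when adjusted over lists.

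Interferon-stimulated genes also rose on this background, 21 of 30 with 1 fall and 8 not called, or 26 and 1 when adjusted over the list alone. Lgals3bp, a secreted glycoprotein induced by interferon (1.24 ± 0.16), Oasl2, a relative of the 2'-5' oligoadenylate synthetases (1.55 ± 0.24), and Ifi35 (0.84 ± 0.16) rose, and Stat2, a transcription factor of interferon signalling, fell (−0.50 ± 0.13). Reads may be shared within the Oas and Gbp families. The median was 0.83 (camera, adjusted p = 4.55e-15), with adjusted p = 0.0834 with an estimated correlation. Of 21 microglia genes 13 rose, none fell and 8 were not called, with 14 rising over the list alone, among them C1qb, a complement subunit made by microglia (0.77 ± 0.10). The microglia median was 0.52 (camera, adjusted p = 1.23e-10), with adjusted p = 0.0667 with an estimated correlation. Genes of phagocytic microglia rose in 7 of 18 cases, 13 over the list alone, including the growth factor Igf1 (1.03 ± 0.10).

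Reactive astrocyte, Purkinje cell and choroid plexus lists rose too in P5 Rnaseh2b/Atm against libraries labelled Atm. Reactive astrocyte genes rose in 6 of 13 cases, 9 over the list alone, including Hspb1, a small heat shock protein (1.21 ± 0.15). That median was 0.61 (camera, adjusted p = 5.26e-06), with adjusted p = 0.0925 with an estimated correlation. Purkinje cell genes rose in 9 of 15 cases, 13 over the list alone, including the glutamate transporter Slc1a6 (0.98 ± 0.16). The Purkinje list value was −1.42 in Atm 1, −0.10 in Atm 2 and 0.34 in Atm 3, and 0.52 to 0.97 in Rnaseh2b/Atm. The median of the list was 0.98 (camera, adjusted p = 2.38e-09), with adjusted p = 0.0925 with an estimated correlation. Choroid plexus genes rose in 8 of 10 cases, again 8 over the list alone, including the thyroid hormone carrier Ttr (4.47 ± 1.07). The channel subunit Kcne2, which is not on that list, rose by 4.21 ± 1.01. Ttr was at 3.38, 5.65 and 9.87 log2 CPM in the libraries labelled Atm and at 10.3 or more in Rnaseh2b/Atm, so 2 of the 3 libraries labelled Atm held low values. The choroid plexus median was 2.67 (camera, adjusted p = 3.58e-06), with adjusted p = 0.126 with an estimated correlation. Myh3 (3.55 ± 0.46) and the unconventional myosin Myo7a (2.97 ± 0.68) also rose, and Hddc3, a hydrolase (−1.72 ± 0.52), and Dmrta1, a transcription factor (−1.49 ± 0.41), fell. Without Atm 2 the count was 875 and without Rnaseh2b/Atm 2 it was 874, and with only both groups in the fit 343 were called. FPKM plus 0.1 gave 1359 higher and 170 lower, and leaving out both libraries that stood apart gave 1547 and 1955.

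Against control, the P5 Rnaseh2b/Atm libraries showed 999 rises and 521 falls (limma, n = 4 and 3), which asked for the joint effect of both genotypes. Of 34 p53 targets 14 rose, 20 were not called and 16 rose over the list alone, with a median of 0.33 (camera, adjusted p = 3.32e-08, and adjusted p = 0.0204 with an estimated correlation). Ccng1 rose by 1.08 ± 0.09, Ephx1 by 1.36 ± 0.12, Dcxr by 1.38 ± 0.15 and Aen, a nuclease of apoptosis, by 0.75 ± 0.09. Of 30 interferon-stimulated genes 16 rose and 14 were not called, or 24 rose and 1 fell over the list alone. Their median was 0.74 (camera, adjusted p = 3.35e-11), with adjusted p = 0.198 with an estimated correlation. Microglia genes rose in 14 of 21 cases, 15 over the list alone, with a median of 0.61 (camera, adjusted p = 4.71e-12, and adjusted p = 0.039 with an estimated correlation). Without the libraries that stood apart, adjusted p with an estimated correlation was 0.474 for p53 targets and 0.262 for microglia genes (camera). C1qb (0.79 ± 0.10), C1qc (0.66 ± 0.09), the chemokine receptor Cx3cr1 (0.51 ± 0.07) and the growth factor receptor Csf1r (0.57 ± 0.08) were among them.

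Several other P5 list values lay above control in Rnaseh2b/Atm with both groups apart (exact permutation p = 0.0286 each, or 0.0889 adjusted over lists). These were choroid plexus (1.28), Purkinje cell (0.824), reactive astrocyte (0.607), complement (0.447), immediate early (0.344) and stress response genes (0.144). Myh3 (3.23 ± 0.46), Myo7a (2.42 ± 0.68), Eda2r, a p53-induced receptor (1.95 ± 0.59), Scara5, a scavenger receptor (1.80 ± 0.25), and Fgf15, a growth factor (1.78 ± 0.46), rose. RNaseP_nuc, whose reads may be shared with copies elsewhere, fell the most (−7.15 ± 2.04), as it did against libraries labelled Atm (−10.96 ± 2.04). Dmrta1 (−1.95 ± 0.41), Hddc3 (−1.90 ± 0.52), Cadps2, a secretion factor of granule cells (−1.59 ± 0.47), Nhlh2, a neuronal transcription factor (−1.53 ± 0.45), and Barhl1, a transcription factor of granule progenitors (−1.18 ± 0.32), fell. The count was 4023 without control 2, 688 without control 3, 988 without Rnaseh2b/Atm 1, 745 without Rnaseh2b/Atm 2, 940 without Rnaseh2b/Atm 3, 822 with Xist as a covariate and 42 with only both groups in the fit. The split was 952 and 760 by voom, 1108 and 221 by FPKM plus 0.1, and 2949 and 3431 without both libraries that stood apart.

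The comparison of Rnaseh2b/p53 with p53 at P5 asked what Rnaseh2b deletion changed when p53 was also lost. Only 19 genes rose and 10 fell (limma, n = 4 and 3). None of 34 p53 targets was called, and their median was 0.03 (camera, adjusted p = 0.896). Ccng1 stood at 0.07 ± 0.09. Interferon-stimulated genes rose in 3 of 30 cases with 27 not called, and 23 rose over the list alone, with a median of 0.66 (camera, adjusted p = 3.17e-43, and adjusted p = 0.0065 with an estimated correlation). The list value had an exact permutation p of 0.0571. The called members were Oasl2 (1.44 ± 0.24), Ifi35 (0.85 ± 0.16) and Gbp2, a guanylate-binding protein (0.83 ± 0.16). Complement and antigen presentation genes had a median of 0.29 (camera, adjusted p = 8.97e-09, and adjusted p = 0.0239 with an estimated correlation), with none of 10 called and 4 rising over the list alone. Without the libraries that stood apart, adjusted p with an estimated correlation was 0.0426 for interferon-stimulated and 0.0951 for complement genes (camera). Myh3 (2.57 ± 0.46), the transporter Slco1c1 (0.57 ± 0.11) and the microglial receptor Gpr34 (0.52 ± 0.09) also rose, and the oxygenase Jmjd5 (−0.83 ± 0.15) and the ribosomal gene Rpl3 (−0.81 ± 0.15) fell. The pseudogene Rpl3-ps1, whose reads may be shared with Rpl3, rose by 0.64 ± 0.10. Less Rpl3 transcript therefore need not lie behind that fall. RNaseP_nuc fell the most (−11.36 ± 2.04). Of muscle genes, again named after their values were seen, Myog (7.12 ± 1.14), Tnnc2 (3.58 ± 0.50), Tnni1 (3.37 ± 0.45) and Mylpf (1.91 ± 0.34) rose, but neither they nor Myh3 were called in Rnaseh2b/p53 against control, and Tnni1 fell by 2.49 ± 0.48 in p53. The count was 13, 16 and 9 without p53 1, p53 2 and p53 3, and 7, 8, 6 and 11 without Rnaseh2b/p53 1, 2, 3 and 4. It was 61 with only both groups in the fit, 14 with Xist as a covariate, 46 without the libraries that stood apart and 5 among genes with a mean of at least 1 log2 CPM in a stricter filter.

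Against control, P5 Rnaseh2b/p53 had 31 rises and 35 falls (limma, n = 4 and 3), asking for the joint effect of both deletions. Interferon-stimulated genes rose in 2 of 30 cases, 21 over the list alone, namely Oasl2 (1.33 ± 0.24) and Rtp4, an inducible chaperone (1.37 ± 0.26). Their median was 0.60 (camera, adjusted p = 2.31e-23), with adjusted p = 0.0825 with an estimated correlation and an exact permutation p of 0.0571 for the list value. None of 34 p53 targets was called, and the list had a median of −0.02 (camera, adjusted p = 0.103). Apobec3, an antiviral cytidine deaminase (0.95 ± 0.16), and Tmod3, an actin-capping protein (0.68 ± 0.13), rose. Slc5a5, an iodide transporter (−1.23 ± 0.25), Dera (−1.03 ± 0.13) and Dctd, a deaminase of deoxycytidylate (−0.83 ± 0.12), fell. The count was 190 without control 1, 28 without control 2, 28 without control 3, 20 without Rnaseh2b/p53 2, 29 without Rnaseh2b/p53 3 and 27 without Rnaseh2b/p53 4. It was 105 by voom, 29 with only both groups in the fit, 27 with Xist and 129 with the medulla and pons list as a covariate, and FPKM plus 1 split the calls 48 and 32.

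Whether the Rnaseh2b effect at P5 differed by background was tested as a difference of effects. With and without the Atm label no gene differed (limma, 0 called, smallest adjusted p = 0.0598), with 884 at an unadjusted p below 0.05, 0 by voom and 1 by FPKM. List medians differed by 0.14 for p53 targets (camera, adjusted p = 2.64e-04), 0.34 for microglia (7.87e-09), 0.31 for interferon-stimulated genes (3.49e-04) and 0.73 for Purkinje cell genes (8.75e-10). With an estimated correlation adjusted p was 0.142, 0.142, 0.491 and 0.142 (camera). Ccng1 differed by 0.55 ± 0.13 (limma, adjusted p = 0.29). With and without p53 only the gene model Gm15920, named after its value was seen, differed (−1.08 ± 0.13, limma adjusted p = 0.0036), and 1011 genes had an unadjusted p below 0.05. The p53 target list differed by a median of −0.31 (camera, adjusted p = 2.37e-05), with adjusted p = 0.0782 with an estimated correlation. None of its 34 members was called and 5 were lower over the list alone. Interferon-stimulated genes were not called as a list between those backgrounds (median 0.10, camera adjusted p = 0.0976), which does not show that the effects were equal. Leaving out control 1, control 3, Rnaseh2b 3, Rnaseh2b/Atm 3 or Rnaseh2b/Atm 4 gave 3, 5, 1, 8 and 11 calls for the Atm difference. For the p53 difference, leaving out control 1, 2 or 3 gave 16, 2 and 3, and leaving out Rnaseh2b 1, Rnaseh2b 2 or p53 1 gave 2, 5 and 6.

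At P28 the comparison of Rnaseh2b with control asked what RNase H2 loss changed once the cerebellum had formed. Of 16530 genes, 471 rose and 390 fell (limma, n = 5 and 5). The alarmin Il33 rose by 1.14 ± 0.10 log2 (limma, adjusted p = 3.3e-06), the GABA receptor subunit Gabra5 by 1.48 ± 0.36, the membrane glycoprotein Igsf1 by 1.38 ± 0.24, the synaptic organizer Cbln4 by 1.29 ± 0.33 and the Wnt inhibitor Wif1 by 1.24 ± 0.23. Falls were seen in Rhbdf2, a regulator of growth factor shedding (−1.17 ± 0.25), Scx, a transcription factor (−1.11 ± 0.27), Sla, an adaptor of receptor signalling (−0.94 ± 0.09), and the peptide Npy (−0.92 ± 0.21). Kit, a receptor of molecular layer interneurons, fell by 0.61 ± 0.05.

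Of the lists at P28 in Rnaseh2b, mitochondrially encoded genes had the smallest camera p. They rose in 11 of 24 cases, 14 over the list alone, including the complex I subunits mt-Nd1 (0.37 ± 0.08) and mt-Nd5 (0.35 ± 0.08). The median was 0.27 (camera, adjusted p = 9.89e-07), with adjusted p = 0.34 with an estimated correlation, and the list value had an exact permutation p of 0.00794, or 0.0536 adjusted over lists. Of 34 p53 targets 3 rose and 31 were not called, or 6 rose and 4 fell over the list alone. These were Pmaip1 (1.12 ± 0.20), Psrc1, a microtubule protein (1.10 ± 0.27), and Abhd4, a lipase (0.21 ± 0.06). The p53 list was not called (median 0.06, camera adjusted p = 0.338), although its value lay 0.0736 above control with both groups apart (exact permutation p = 0.00794, or 0.0536 adjusted over lists). The Purkinje cell and astrocyte list values had the same permutation p. None of 35 interferon-stimulated genes was called, and their median was 0.29 (camera, adjusted p = 0.029), with adjusted p = 0.748 with an estimated correlation and an exact permutation p of 0.111 for the list value. That value was 0.82 in Rnaseh2b 3 and at most 0.17 in the other libraries of its group. Purkinje cell genes had 1 fall in 15, or 6 rises and 1 fall over the list alone, with a median of 0.17 (camera, adjusted p = 0.0394) and adjusted p = 0.605 with an estimated correlation. Astrocyte genes rose in 3 of 14 cases, also 3 over the list alone, including the water channel Aqp4 (0.50 ± 0.08) and the connexin Gja1 (0.35 ± 0.07), and the list was not called (median 0.08, camera adjusted p = 0.0672).

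Single libraries moved the P28 Rnaseh2b count in both directions. It was 287, 195 and 257 without Rnaseh2b 1, 2 and 3, and 394, 2564, 358, 316 and 187 without control 1, 2, 3, 4 and 5. With only both groups in the fit it was 1532, and with the midbrain list as a covariate it was 2113. Splits were 549 higher and 285 lower by FPKM plus 0.1, and 596 and 322 after quantile scaling.

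The P28 libraries labelled Atm were set against control for the same question about the Atm label, and 156 genes rose and 152 fell (limma, n = 5 and 5). No list was called by camera, with a median of 0.03 for p53 targets (adjusted p = 0.527) and −0.09 for interferon-stimulated genes (adjusted p = 0.527). Gcnt1, a glycosyltransferase (2.38 ± 0.29 log2, limma adjusted p = 0.00011) and Prtg, a neural receptor (2.21 ± 0.36), rose. Bub1b, a spindle checkpoint kinase (−2.75 ± 0.64), Ctsc, a lysosomal protease (−2.01 ± 0.49), Pla2g4b, a phospholipase (−1.90 ± 0.23), and Chrna3, a nicotinic receptor subunit (−1.49 ± 0.27), fell. Fabp7 (0.66 ± 0.12) and Aqp4 (0.40 ± 0.08), both astrocyte genes, and the microglial receptor P2ry12 (0.40 ± 0.09) rose. Of genes of the daily clock, Dbp (−1.15 ± 0.17), Nr1d1 (−0.52 ± 0.10) and Per3 (−0.42 ± 0.10) fell and Arntl (0.57 ± 0.14) rose. They were named after their values were seen, and no list of clock genes was tested. The counts may therefore hold differences between these samples other than the Atm label. The count was 199 without control 1, 1102 without control 2, 185 without control 4, 619 without Atm 3 and 203 without Atm 4. It was 194 with only both groups in the fit and 165 with the midbrain list as a covariate.

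The P28 comparison of Rnaseh2b/Atm with libraries labelled Atm asked what Rnaseh2b deletion changed on the Atm background. Here 4952 genes rose and 5130 fell (limma, n = 5 and 5), 2061 of them by over 2-fold. Atm transcripts were at 4.05 ± 0.05 log2 CPM in Rnaseh2b/Atm and 4.79 ± 0.15 in libraries labelled Atm. The contrast may therefore also hold a difference in Atm itself. Th, the enzyme that limits dopamine synthesis, rose by 7.70 ± 0.23 log2, from 1.29 to 9.00 log2 CPM (limma, adjusted p = 1.5e-14). Ube2c, a mitotic ubiquitin-conjugating enzyme, rose by 5.43 ± 0.24. Shox2, a transcription factor of midbrain and thalamus (7.76 ± 1.73), Cbln2, a synaptic organizer (5.53 ± 1.01), the neuropeptide Tac1 (5.47 ± 0.66), the cadherin relative Cdhr1 (4.86 ± 0.65), Fibcd1, a chitin-binding receptor (4.81 ± 0.56), and the calcium-binding Cpne5 (4.77 ± 0.78) rose as well. With the midbrain list as a covariate, Shox2 changed to −2.58, Cbln2 to −0.56 and Cpne5 to −0.04, whereas Th stayed at 7.19. A midbrain gene such as Shox2 may follow that list in any case. Both groups were also fully apart on it, so these changes cannot tell tissue from genotype. Tgm5, a transglutaminase (−4.94 ± 0.16), Sla (−3.62 ± 0.09), Ldoc1, a nuclear factor (−3.54 ± 0.21), Tssk5, a kinase (−3.51 ± 0.20), Car4, a carbonic anhydrase (−3.35 ± 0.11), and Hkdc1, a hexokinase (−3.24 ± 0.12), fell. Kit fell by 2.06 ± 0.05.

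Mature granule neuron genes fell in 13 of 15 cases on this background, 13 over the list alone, with 2 not called. Among them were Grin2c, an NMDA receptor subunit of mature granule neurons (−2.56 ± 0.15), Neurod1, a transcription factor of granule neurons (−1.95 ± 0.17), and Gabrd, a GABA receptor subunit (−1.94 ± 0.15). The median was −1.75 (camera, adjusted p = 1.07e-05), with adjusted p = 0.477 with an estimated correlation. Myelin genes fell in 15 of 16 cases, also 15 over the list alone, including Aspa, an enzyme of acetate supply to oligodendrocytes (−0.86 ± 0.17), and Fa2h, a lipid hydroxylase (−1.26 ± 0.25). Their median was −0.88 (camera, adjusted p = 0.0042), with adjusted p = 0.613 with an estimated correlation. DNA replication genes fell in 12 of 21 cases and rose in 2, or 13 and 3 over the list alone, with a median of −0.34 (camera, adjusted p = 0.0372) and adjusted p = 0.131 with an estimated correlation. List values gave an exact permutation p of 0.00794 for granule neurons and 0.0159 for myelin.

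Lists of interferon-stimulated, microglia, complement and reactive astrocyte genes rose in P28 Rnaseh2b/Atm against libraries labelled Atm. Of 35 interferon-stimulated genes 32 rose, 1 fell and 2 were not called, the same over the list alone, including Ifit2, which binds foreign RNA (2.02 ± 0.22), and Lgals3bp (1.79 ± 0.22). Their median was 1.26 (camera, adjusted p = 2.07e-06), with adjusted p = 0.509 with an estimated correlation. Microglia genes rose in 20 of 21 cases, also 20 over the list alone, including Olfml3 (1.5 ± 0.14) and C1qb (0.99 ± 0.12), with a median of 0.72 (camera, adjusted p = 2.07e-06) and adjusted p = 0.477 with an estimated correlation. Genes of phagocytic microglia rose in 10 of 15 cases and fell in 1, including Spp1, a secreted phosphoprotein (2.02 ± 0.18), with a median of 0.40 (camera, adjusted p = 0.00153) and adjusted p = 0.131 with an estimated correlation. Reactive astrocyte genes rose in 9 of 13 cases and fell in 1, or 10 and 1 over the list alone, including the filament Gfap (2.18 ± 0.22) and the ferroxidase Cp (1.25 ± 0.07). That median was 1.20 (camera, adjusted p = 0.00165), with adjusted p = 0.099 with an estimated correlation. Complement genes rose in 10 of 12 cases and fell in 1, including C4b (2.25 ± 0.18) and C3 (2.11 ± 0.29), with a median of 0.79 (camera, adjusted p = 0.00976) and adjusted p = 0.477 with an estimated correlation. Of 34 p53 targets 17 rose and 13 fell, the same over the list alone, and camera did not call the list (median 0.30, adjusted p = 0.183). Its value was 0.297 higher with both groups apart (exact permutation p = 0.00794, or 0.0165 adjusted over lists), so the 2 list tests differed. The rising p53 targets included Eda2r (2.72 ± 0.27), Pmaip1 (2.32 ± 0.20) and Sesn2, a stress sensor (0.77 ± 0.08).

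**Figure D3:**
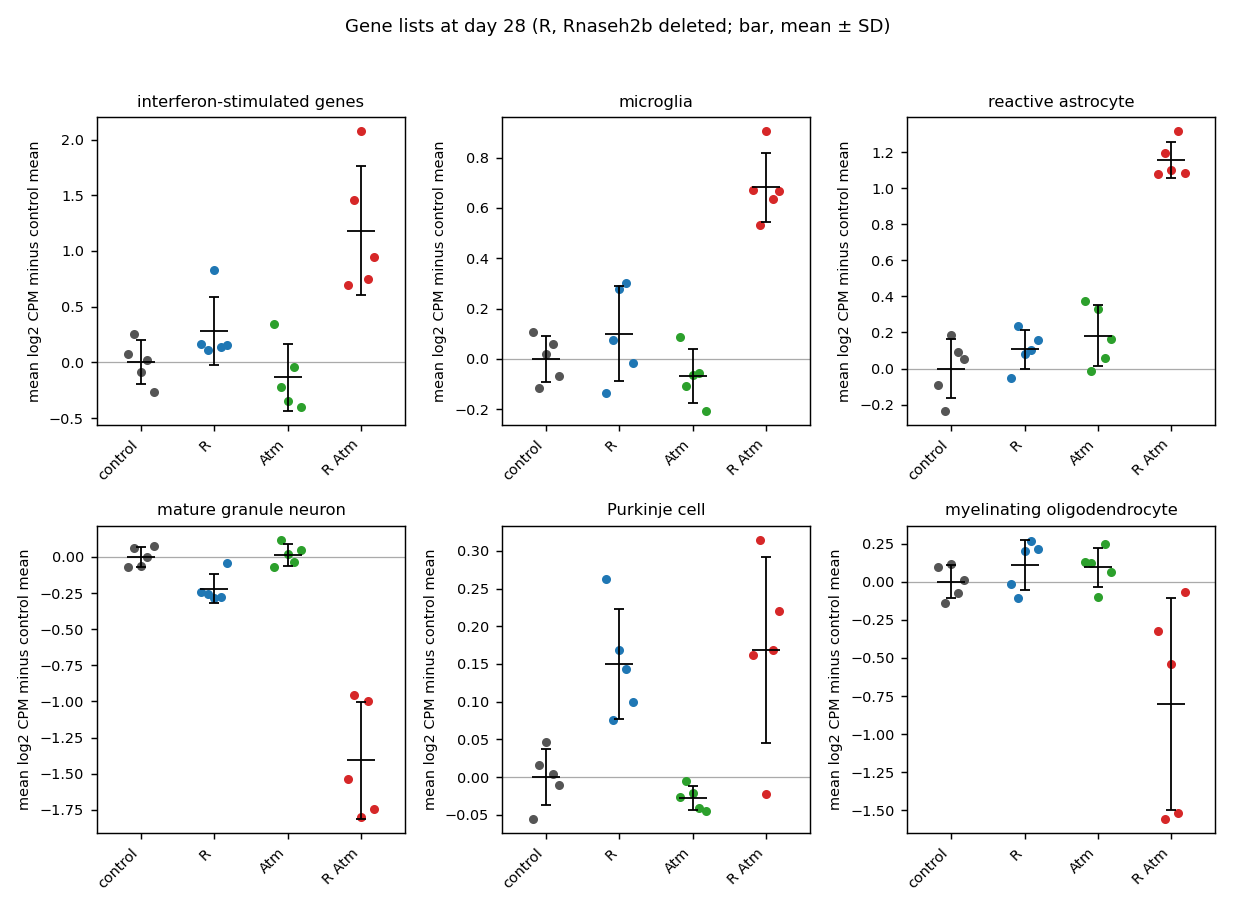
Values of 6 gene lists in P28 libraries, in log2 relative to the control mean, with R for Rnaseh2b deleted. Points are libraries and bars are means ± SD, for example −1.41 ± 0.41 for mature granule neuron genes in Rnaseh2b/Atm.

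Against control, P28 Rnaseh2b/Atm had 5202 rises and 5304 falls (limma, n = 5 and 5), which asked for the joint effect of both genotypes. The cell cycle inhibitor Cdkn1a rose by 1.61 ± 0.14 log2 (limma, adjusted p = 1.6e-08), from 4.48 ± 0.28 to 6.10 ± 0.26 log2 CPM. Th rose by 7.10 ± 0.23, Ube2c by 4.87 ± 0.24 and Fosb, an activity-induced transcription factor, by 3.96 ± 0.45. Tgm5 fell by 4.91 ± 0.16, Ldoc1 by 3.85 ± 0.21 and Car9, a carbonic anhydrase, by 3.60 ± 0.14. Shox2 rose by 4.13 ± 1.73, which changed to −2.63 with the midbrain list as a covariate, and Lhx2 changed to −0.44. Of 34 p53 targets 18 rose and 8 fell, and camera did not call the list (median 0.24, adjusted p = 0.0827). Its value was 0.327 higher with both groups apart (exact permutation p = 0.00794, or 0.0153 adjusted over lists). Interferon-stimulated genes rose in 32 of 35 cases and fell in 1, the same over the list alone, with a median of 1.22 (camera, adjusted p = 1.08e-05) and adjusted p = 0.627 with an estimated correlation. Granule neuron genes fell in 13 of 15 cases and rose in 2, with a median of −1.70 (camera, adjusted p = 2.65e-05) and adjusted p = 0.473 with an estimated correlation. All 16 myelin genes fell, including Mbp (−0.83 ± 0.23), with a median of −0.74 (camera, adjusted p = 0.0105) and adjusted p = 0.627 with an estimated correlation. The interferon signalling gene Stat2 fell by 1.29 ± 0.09, and Gad2, a GABA-synthesizing enzyme, rose by 1.55 ± 0.10. Foxp2, a transcription factor of Purkinje cells, rose by 1.65 ± 0.18.

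Whether the P28 Rnaseh2b effect differed with the Atm label was tested as a difference of effects, and 3093 genes were higher and 3141 lower (limma, n = 5 in each of 4 groups). Atm transcripts were lower in Rnaseh2b/Atm than in libraries labelled Atm, so these counts may also hold a difference in Atm itself. The difference was 7.12 ± 0.33 log2 for Th (limma, adjusted p = 3.7e-11), 1.37 ± 0.20 for Cdkn1a, −2.69 ± 0.12 for Sla and −4.79 ± 0.22 for Tgm5. Granule neuron genes were lower in 12 of 15 cases, 12 over the list alone, including Grin2c (−2.01 ± 0.22), with a median of −1.52 (camera, adjusted p = 1.18e-06) and adjusted p = 0.366 with an estimated correlation. Microglia genes were higher in 14 of 21 cases, 15 over the list alone, including the lysosomal protease Ctss (1.05 ± 0.16), with a median of 0.57 (camera, adjusted p = 4.72e-06) and adjusted p = 0.366 with an estimated correlation. Interferon-stimulated genes were higher in 19 of 35 cases and lower in 1, or 27 and 1 over the list alone, with a median of 0.99 (camera, adjusted p = 1.78e-05) and adjusted p = 0.533 with an estimated correlation. Myelin genes were lower in 13 of 16 cases, 15 over the list alone, with a median of −1.01 (camera, adjusted p = 5.14e-04) and adjusted p = 0.533 with an estimated correlation. The p53 targets split into 12 higher and 5 lower and were not called as a list (median 0.22, camera adjusted p = 0.182). With the midbrain list as a covariate 3300 genes were called, and Cbln2 changed to −0.45 and Shox2 to −1.75.

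At 9 weeks the comparison of Rnaseh2b with control asked what RNase H2 loss changed in the adult cerebellum. Of 15078 genes, 1599 rose and 1443 fell (limma, n = 7 and 7), only 38 of them by over 2-fold. The securin gene Pttg1 rose by 1.89 ± 0.63, Igsf1 by 1.64 ± 0.14 (limma, adjusted p = 1.2e-05), Wif1 by 1.36 ± 0.23, the ion channel subunit Accn4 by 1.27 ± 0.25 and Cpxm2, a peptidase relative, by 1.26 ± 0.16. Sla fell by 1.72 ± 0.11 (limma, adjusted p = 5e-07), the lectin receptor Asgr1 by 1.18 ± 0.17, Kit by 1.03 ± 0.11, the protease Adamts15 by 0.95 ± 0.08 and the guidance cue Ntn1 by 0.90 ± 0.09. Granule neuron genes fell in 9 of 15 cases with 6 not called, or 13 fell and 1 rose over the list alone. They included the glutamate transporter Slc17a7 (−0.38 ± 0.07), the cadherin Fat2 (−0.50 ± 0.10) and Grin2c (−0.36 ± 0.08). That median was −0.34 (camera, adjusted p = 1.57e-05), with adjusted p = 0.329 with an estimated correlation, and the list value had an exact permutation p of 5.83e-04.

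Immune and glial lists rose at 9 weeks. Of 31 interferon-stimulated genes 23 rose, 1 fell and 7 were not called, or 26 and 1 over the list alone. Usp18, which removes ISG15 (1.04 ± 0.22), Ifit2 (0.55 ± 0.12) and Ifit1 (0.79 ± 0.17) rose, and Stat2 fell (−0.28 ± 0.07). Their median was 0.53 (camera, adjusted p = 3.56e-10), with adjusted p = 0.329 with an estimated correlation, and an exact permutation p of 0.00233 for the list value. Microglia genes rose in 14 of 21 cases, 18 over the list alone, including C1qc (0.59 ± 0.08) and Tmem119 (0.74 ± 0.10), with a median of 0.45 (camera, adjusted p = 1.53e-10) and adjusted p = 0.329 with an estimated correlation. The reactive astrocyte gene Gfap rose by 0.71 ± 0.10, a single gene that does not speak for its whole list. Astrocyte and Bergmann glia genes rose in 5 of 14 cases, 6 over the list alone, including Aqp4 (0.46 ± 0.06), with a median of 0.18 (camera, adjusted p = 0.0014) and adjusted p = 0.295 with an estimated correlation. Myelin genes rose in 8 of 16 cases, 10 over the list alone, including Cnp (0.29 ± 0.06) and Mobp (0.41 ± 0.11), with a median of 0.29 (camera, adjusted p = 2.24e-04) and adjusted p = 0.421 with an estimated correlation. Of 31 p53 targets 4 rose, 3 fell and 24 were not called, the same over the list alone, and the median was −0.03 (camera, adjusted p = 0.9999). Phlda3, an inhibitor of Akt, rose by 0.66 ± 0.13, Ddb2, a DNA damage sensor, fell by 0.26 ± 0.07 and Ccng1 stood at 0.00 ± 0.07.

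Within the 9-week runs, 1084 genes were called in codes 11 to 16 and 90 in codes 50 to 58, and 1915 without control 3. With the midbrain list as a covariate 19 genes were called, and Accn4 changed to −0.04. That list, chosen after the data had been seen, was 0.87 ± 0.23 log2 in Rnaseh2b, from 0.56 to 1.17, and −0.57 to 0.32 in control, so both groups were fully apart on it. Only 4 members of the list were tested at 9 weeks. At P28 the list had 9 members and was 3.99 ± 0.48 in Rnaseh2b/Atm, 1.37 ± 2.0 in Rnaseh2b and −2.11 ± 1.87 in libraries labelled Atm.

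**Figure D4:**
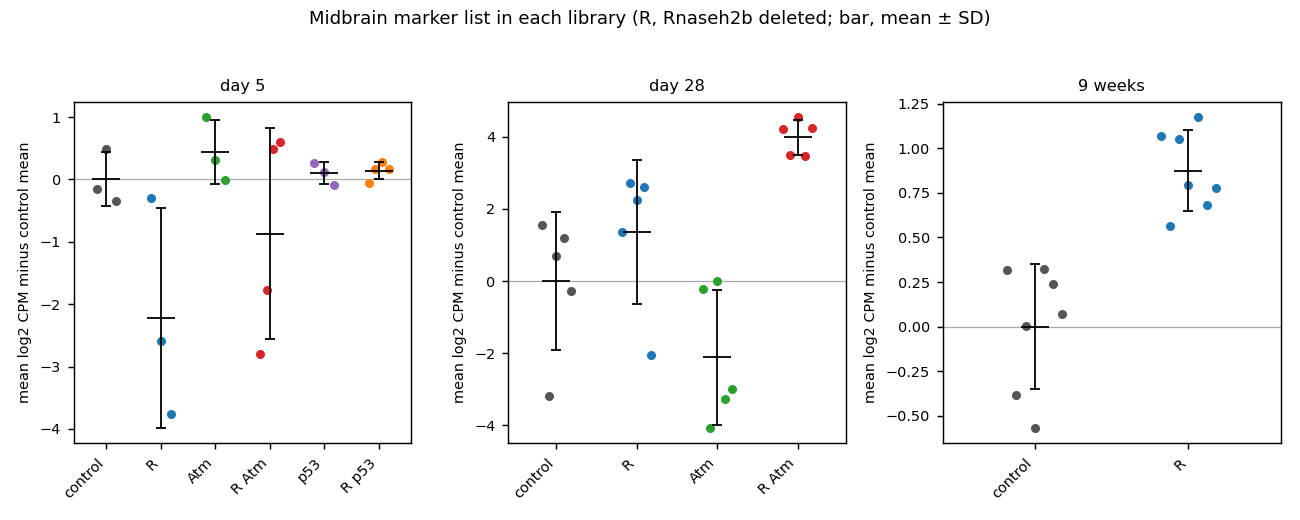
Value of the midbrain list per library at P5, P28 and 9 weeks, in log2 relative to the control mean, with R for Rnaseh2b deleted. The list had 10 members at P5, 9 at P28 and 4 at 9 weeks. Points are libraries and bars are means ± SD, for example 0.87 ± 0.23 in 9-week Rnaseh2b.

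The Rnaseh2b effect was compared between ages through overlaps of called genes, which share no libraries. Of 14610 genes tested at both 9 weeks and P28, 224 rose at both, with 48.5 expected (adjusted p = 2.66e-99, hypergeometric test on limma calls). For falls the overlap was 148, with 35.7 expected (adjusted p = 4.51e-56, on limma calls). It was 240 with the replicate number as a block and 9 with the midbrain covariate, against 372 in both directions. The hypergeometric test takes genes as independent, so its p does not measure the spread between samples. As lists in P28 Rnaseh2b, the 9-week rises and falls had adjusted p = 0.151 and 0.532 (camera with an estimated correlation). The P28 lists at 9 weeks had 0.106 and 0.178 by the same test. Between 9 weeks and P5, 10 genes rose at both, with 4.50 expected (adjusted p = 0.0163, on limma calls), and 7 fell at both, with 4.30 expected. P28 and P5 shared 4 rises, with 1.34 expected, and 1 fall, with 1.32 expected. Besides Rnaseh2b, only Vwa5a was called at all 3 ages, rising by 0.28, 0.32 and 0.37 log2 at 9 weeks, P28 and P5.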

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

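All tests of explanations in this part were chosen after the results were seen. A single library far from the rest of its group was looked for in 110 sets of 4 to 10 libraries, and 10 were found, while chance alone singles out about 1 in 20. At 9 weeks Rnaseh2b 3 had the lowest granule neuron value of its group (−0.685, next −0.304) and the highest myelin value (0.844, next 0.312), and control 4 the lowest cell cycle value (−0.284, next −0.0293). At P28 Rnaseh2b 3 had a high interferon-stimulated value (0.825, next 0.168), Rnaseh2b 5 a granule neuron value closest to control (−0.0428, next −0.246), and Atm was high in Rnaseh2b 1 (4.89 log2 CPM, next 4.69) and in control 2 (4.94, next 4.82). At P5 Rnaseh2b/Atm 4 had the lowest Purkinje cell value (0.517, next 0.897) and the lowest Trp53 (2.98 log2 CPM, next 3.44), and Rnaseh2b/p53 3 had 711 M reads in genes (next 91.4 M). A difference between groups singled out 3 further results, namely the 6234 genes of the P28 difference of effects, the 1 gene of the P5 difference with p53, and the p53 target list there with a median of −0.31 (camera adjusted p = 2.37e-05, with adjusted p = 0.0782 with an estimated correlation, and limma calling none of 34 members).

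The first pattern is the midbrain signal in P28 Rnaseh2b/Atm and 9-week Rnaseh2b, whereas the list differed from control by −2.22 in P5 Rnaseh2b (exact permutation p = 0.2) and by 1.37 in P28 Rnaseh2b (exact permutation p = 0.317), with overlapping groups in both. In P28 Rnaseh2b/Atm the list was 3.99 ± 0.48 log2 above control and 6.10 above libraries labelled Atm (exact permutation p = 0.00794, or 0.0492 adjusted), and the forebrain list was also higher there, by 1.91 and 2.91 (exact permutation p = 0.00794), so the signal was not of midbrain genes alone. More midbrain tissue in the dissection could raise such genes. With the list as a covariate 6901 genes were still called against libraries labelled Atm. But the list ran from 3.46 to 4.54 in Rnaseh2b/Atm and from −4.07 to 0.01 in libraries labelled Atm. With these groups fully apart, the covariate cannot say whether tissue is the whole cause. A lower share of granule neurons with all else unchanged would raise microglia and myelin genes alike, yet they differed by 1.65 log2. At 9 weeks the covariate left 19 calls, but since both groups were fully apart on the list, tissue and genotype cannot be told apart there.

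The second pattern is that P5 control 2 and Atm 1 stood apart, at 44.8 and 77.6 on a first component holding 35.0% of the variance. They were the 2 highest libraries for ventral midbrain genes (lower rank 2), which fits extra midbrain tissue in them. But Atm 2 was nearly as high (2.38, against 2.93 in Atm 1 and 2.55 in control 2) and did not stand apart (12.2), so such tissue may not be all that sets them apart, and Atm 1 was almost without the granule lineage genes Neurod1 (2.01 log2 CPM), Atoh1 (−3.42) and Pax6 (3.33). For medulla and pons genes their lower rank was 10, which speaks against tissue from there. A trend with gene length was small in both (larger absolute Spearman correlation 0.0357, against 0.197 in Rnaseh2b/p53 4). This speaks against such a trend as the cause, but other differences in RNA quality were not tested.

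The third pattern is the rise of interferon-stimulated genes, which could come from more microglia. At P5 the list rose beyond the microglia list by 0.53 log2 in Rnaseh2b/p53 against p53 (exact permutation p = 0.0571, or 0.133 adjusted). Against control it rose by 0.83 beyond that list (exact permutation p = 0.0286, or 0.133 adjusted). In both the groups were apart, which a larger share of microglia alone would not give. But neither adjusted p was below 0.05, so such a share is not excluded. In Rnaseh2b against control (0.34, exact permutation p = 0.2) and Rnaseh2b/Atm against Atm (0.32, exact permutation p = 0.0857) the groups overlapped. In P28 Rnaseh2b/Atm against Atm the excess was 0.57 (exact permutation p = 0.0397, or 0.133 adjusted), where both explanations cannot be told apart, and at 9 weeks it was 0.086 (exact permutation p = 0.357), which more microglia could account for. The test against control at P5 was added after the first result had been seen. More males among Rnaseh2b/p53 would not explain the P5 rise, since the median was 0.76 with Xist as a covariate.

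Counts of calls were compared with those from other splits of the same libraries. At 9 weeks 1 of 100 splits, the real one, reached the 3042 calls, and the highest other had 2. At P28, 2 of 100 reached the 861 of Rnaseh2b against control, where another split had 3592, several times the real count, which points to structure among the samples beyond genotype. The real split alone, 1 of 100 each, reached the counts for Atm against control (308, highest other 2), Rnaseh2b/Atm against control (10506, highest other 5483) and against Atm (10082, highest other 5763), and the P28 difference (6234, highest other 4848). At P5 with 4 and 3 libraries the real split alone, 1 of 35, reached 1520 for Rnaseh2b/Atm against control (highest other 591), 66 for Rnaseh2b/p53 against control (1), 1465 for Rnaseh2b/Atm against Atm (929) and 29 for Rnaseh2b/p53 against p53 (16). With 3 and 3 libraries 10 splits are too few for a share below 0.05, with 105 calls for Rnaseh2b and 15 in the highest other split, and 27 for p53 and 4. For P5 Atm against control all 10 splits reached the real count of 0, as any split must, so that share decides nothing. The highest other split had 7671, which again points to structure among the samples. All 100 splits likewise had to reach 0 for the P5 difference with Atm (highest other 2343), and 21 of 100 reached 1 for that with p53 (highest other 9).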

How the results depend on the processing

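Results were recomputed with a stricter filter, log2 of FPKM plus 0.1 or 1, quantile scaling, no variance trend, Xist as a covariate, fits of only both compared groups, voom on recovered reads, the replicate number as a block and leaving out each library, and covariates for tissue lists and the removal of libraries that stood apart were chosen after seeing the data. The edgeR and DESeq2 fits chosen at the start were not run, since the deposited values are log2 CPM, and voom took their place. Of the values of named genes, 16431 kept their call and side or were called in neither fit, whatever their sign. Another 1899 kept their side but lost their call, 17 gained a call on the same side, and 11 with a call in either fit changed side. For all changes below the cause was not tested, apart from fewer samples or genes where the setting itself removes them. At 9 weeks the 3042 calls became 1084 with codes 11 to 16 alone, 90 with codes of 50 and above alone, and 19 with the midbrain covariate. That covariate gave 2113 and 165 for P28 Rnaseh2b and Atm against control, 3300 for the P28 difference of effects, 1 for P5 Rnaseh2b against control and 11 for the P5 difference with Atm, where 0 were called in the main result. It reversed Accn4 (−0.0440), Ctsz (−0.0934), Ifi27l1 (−0.14) and Trim67 (0.0372) at 9 weeks. At P28 it reversed Lhx2 (−0.44) and Shox2 (−2.63) in Rnaseh2b/Atm against control, Cbln2 (−0.56), Cpne5 (−0.0392) and Shox2 (−2.58) against libraries labelled Atm, and Cbln2 (−0.45) and Shox2 (−1.75) in the difference of effects. With only both groups in the fit the counts were 1532 and 194 for P28 Rnaseh2b and Atm against control. At P5 they were 0 for Rnaseh2b, 3 for p53, 42 for Rnaseh2b/Atm and 29 for Rnaseh2b/p53 against control, 343 for Rnaseh2b/Atm against Atm and 61 for Rnaseh2b/p53 against p53. The filter on a mean of at least 1 log2 CPM gave 63, 14, 38 and 5 calls for P5 Rnaseh2b, p53 and Rnaseh2b/p53 against control and Rnaseh2b/p53 against p53. Xist as a covariate gave 34, 822, 27 and 14 for P5 Rnaseh2b, Rnaseh2b/Atm and Rnaseh2b/p53 against control and Rnaseh2b/p53 against p53, and 2 for the difference with p53. By voom there were 65 and 105 for P5 Rnaseh2b and Rnaseh2b/p53 against control and 2 for the difference with p53. For the P5 difference with Atm, FPKM plus 0.1 and FPKM plus 1 gave 1 each and quantile scaling 5. For the P5 difference with p53, they gave 2 and 4, and 3 came without the trend. The medulla and pons covariate gave 41 and 129 for P5 p53 and Rnaseh2b/p53 against control and 2 for the difference with p53. Without control 2 and Atm 1 at P5 there were 6380 for Rnaseh2b/Atm against control, 3502 against Atm, 46 for Rnaseh2b/p53 against p53 and 7 for the difference with p53. Their removal turned the camera direction of lists, with these medians: cell cycle (−0.0120), DNA replication (−0.0241) and histone genes (−0.17) in P5 Rnaseh2b against control. In p53 against control it turned granule progenitor (−0.0405), cell cycle (−0.0916), choroid plexus (−0.0595), DNA replication (−0.0584) and histone genes (−0.11). In Rnaseh2b/p53 against control it turned granule progenitor, although its median stayed above 0 (0.0024, before 0.31), cell cycle (−0.0177), choroid plexus (−0.0526) and histone genes (−0.20), and against Atm in Rnaseh2b/Atm granule progenitor (−0.48) and cell cycle (−0.52), neither of which had been called before. Of these only the last 2 and histone genes in Rnaseh2b and Rnaseh2b/p53 against control were called after it with the preset correlation (camera, adjusted p = 0.00829, 9.23e-08, 0.0104 and 1.58e-04), and none with an estimated correlation, with which 1 list call in all was left. Of 142 calls of lists in all comparisons, 5 were kept with an estimated correlation. The test fry called 109, but it asks whether a list changed at all, not whether it changed more than other genes. The genes called in Rnaseh2b against control at 9 weeks or P28 were also tested by camera as lists in comparisons at another age, and of 40 such tests called 0 were kept with an estimated correlation. The replicate number as a block gave 1390 at 9 weeks, 13 for P5 p53 against control, 11 for Rnaseh2b/p53 against p53, 1 for the difference with Atm and an overlap between ages of 240, and the midbrain covariate an overlap of 9. Correlations above 0.1 were found for 0 of 7 pairs of libraries with the same number and 18 of 42 with other numbers at 9 weeks, 12 of 30 and 37 of 120 at P28, and 21 of 46 and 47 of 120 at P5. Pairs of the same number were thus slightly more often alike at P28 and P5, but far from all pairs were, and the numbers were not taken as pairing. Leaving out 1 library at a time, counts ran from 1915 to 3251 at 9 weeks. At P28 they ran from 187 to 2564 for Rnaseh2b, 185 to 1102 for Atm and 9887 to 10822 for Rnaseh2b/Atm against control, 9512 to 10272 for Rnaseh2b/Atm against Atm and 5630 to 6857 for the difference. At P5 they ran from 1 to 251 for Rnaseh2b, 0 to 1 for Atm, 3 to 37 for p53, 688 to 4023 for Rnaseh2b/Atm and 20 to 190 for Rnaseh2b/p53 against control. They also ran from 874 to 1861 for Rnaseh2b/Atm against Atm, 6 to 16 for Rnaseh2b/p53 against p53, 0 to 11 for the difference with Atm and 1 to 16 for that with p53. At P5 19.7% to 31.8% of reads named no gene, and depth at 9 weeks was not recovered, so its limit there is not known.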

Other observations

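All tests in this part were chosen after the results were seen. The rise of Th at P28 was not shared in size by other genes of dopamine neurons. In Rnaseh2b/Atm against libraries labelled Atm, limma gave 7.70 ± 0.23 log2 for Th, 0.57 ± 0.18 for the vesicular transporter Slc18a2 (adjusted p = 0.0093) and −2.61 ± 0.45 for the transcription factor Nr4a2 (adjusted p = 5.5e-05). All 5 Rnaseh2b/Atm libraries held the high Th value. The ventral midbrain list, of which Th is 1 of 4 members, was 1.93 ± 0.11 above control. Most of that value came from Th alone, so it does not show a rise of the list as a whole.

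Genes called at 9 weeks in Rnaseh2b were also found in the P28 comparison of Rnaseh2b/Atm with libraries labelled Atm, which shares no library with it. In both, 1187 genes rose, with 469 expected, and 1154 fell, with 450 expected. The midbrain list was higher with Rnaseh2b deleted in both, by 0.87 on 4 members at 9 weeks and by 6.10 on 9 members at P28. With it as a covariate only 19 genes were called at 9 weeks, so this overlap may hold a shared tissue signal. For P28 Rnaseh2b against control the overlaps with that comparison were 439 (141 expected) and 370 (121 expected).

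Of the 200 genes nearest to Rnaseh2b, 57 were called at 9 weeks, 28.5% against 20.5% elsewhere (one-sided Fisher exact p = 0.00444, or 0.0222 adjusted). At P28 there were 16 of 200 (exact p = 0.0729) and at P5 none. Near Atm 7 of 200 were called in P28 libraries labelled Atm (exact p = 0.0688), and near Trp53 none at P5. Gene order came from a newer assembly than the one named for mapping.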
